A study of Mus musculus with 4 samples.

How the data were processed

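RNA was measured in natural killer (NK) cells of the bone marrow of C57BL/6 mice aged 6 to 8 weeks, per the labels. NK cells are innate lymphocytes that kill infected and transformed cells. Cells negative for CD3e and positive for NK1.1 and CD49b were sorted by flow cytometry into Trizol, RNA was purified with a miRNeasy kit, and libraries followed the Smart-seq2 protocol, which amplifies full-length cDNA. The 4 samples form 2 groups of 2 biological replicates, per the series design: littermate controls (Ctrl) and mice that lack the long form of Gabpb1 together with Gabpb2 (dKO).

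The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.36, TopHat2 2.1.1, RSEM 1.3.0, HTSeq 0.6.1 and DESeq2 1.32.0 with the build mm9. Parameters, the annotation release and the strand setting of the counting are not given in the sources used here. For each sample the authors deposited whole-number counts per gene, with 37310 genes and additional rows for reads that were given to no gene. The authors also deposited a table in the RSEM format whose columns hold expected counts, TPM, FPKM and gene lengths, per the file headers. The TPM and FPKM columns, which the authors deposited as length-scaled values, entered no test. The median ratio of the whole-number count to the RSEM expected count was 2.05 in Ctrl 1, 2.05 in Ctrl 2, 2.07 in dKO 1 and 2.07 in dKO 2, over genes with more than 50 expected counts. A common factor cancels in fold changes, but counting error is larger than the whole-number counts alone would give if each fragment was counted more than 1 time.

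Rows that name no gene were kept out of library sizes and tests. Reads outside any annotated gene made up 18.1% of all counted reads in Ctrl 1, 21.5% in Ctrl 2, 23.8% in dKO 1 and 24.3% in dKO 2. Reads with more than 1 possible gene made up 2.34%, 2.22%, 2.23% and 2.20% in the same order. Gene symbols were those that the RSEM tables pair with the Ensembl gene identifiers. Positions are GRCm38 (GENCODE release M21) coordinates found by matching Ensembl gene identifiers, which placed 13391 of the tested genes (96.3%). They are not coordinates of the build used for the counts. Overlapping genes, antisense genes and close gene copies are uncertain, since the strand setting and the treatment of shared reads are not stated.

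Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit) in R 4.3.3, after TMM scaling and a filter for expressed genes with a minimum count of 10, which kept 13904 genes. Fold changes are log2 values of dKO minus Ctrl. The standard error (SE) is the absolute log2 fold change divided by the square root of F, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Levels are CPM, counts scaled by the TMM library size, given as mean ± SD over the 2 libraries of a group. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library, which covers counting error only. A permutation of 2 against 2 libraries cannot give an exact two-sided p below 0.333, so p-values rest on the spread that edgeR shares across genes.

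Gene lists were fixed before the data were examined, 44 in all, and covered NK receptors, maturation, transcription factors, effectors, signalling, migration, mitochondria, metabolism, translation, stress, cell cycle, interferon response and markers of other marrow cells. Of these, 42 were tested as sets with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. An estimated correlation and the fry test were run beside it. Both rest on the spread of only 4 libraries, so a miss there does not show that a list stayed unchanged. The genes named were also set by a rule fixed at that point. It took the GABP subunits and the 12 genes per direction with the largest log2 fold change among changed genes with a mean of at least 10 CPM, separated groups and a symbol that is not a predicted one. It further took up to 4 changed members of each list, or 2 members with the smallest p where none changed, and 11 identity genes of NK cells. Other names are said to have been chosen after their values were seen.

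The procedure was tested on simulated counts with the means, library sizes and fitted spreads of these 4 libraries, drawn independently for each gene. In each of 5 runs 200 of 13904 genes were changed, all among genes with a mean of at least 5 CPM. The procedure found 54.3% of planted changes of 2-fold, 96.7% of 4-fold and 99.7% of 8-fold, and 8.44% of its calls were false. These shares do not cover changes in genes below that level. Runs without any planted change gave a mean of 0.2 calls. Alternatives fixed at the start were other scalings, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a fit that is not robust, the RSEM expected counts rounded to whole numbers, the replicate number as a block, other thresholds and leaving out each library in turn. Counts of changed genes without X and Y, and without the surroundings of Gabpb1 and Gabpb2, were added after the data had been seen.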

Results

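Bone marrow NK cells were profiled by RNA sequencing in 2 Ctrl and 2 dKO libraries to find transcripts that differ between them. GABP is an Ets-family transcription factor in which Gabpa binds DNA and Gabpb1 or Gabpb2 pair with it. Gene counts summed to 34724516 in Ctrl 1, 33299226 in Ctrl 2, 31469644 in dKO 1 and 30233870 in dKO 2. Genes with at least 1 count numbered 15921, 18206, 19450 and 19220 in the same order, so both dKO libraries had more detected genes than both Ctrl libraries. Across genes, log2 CPM correlated with r = 0.9609 between the Ctrl libraries, 0.9732 between the dKO libraries and 0.9483 to 0.9614 between groups. Ctrl 2 thus correlated with dKO 1 (0.9614) as highly as with Ctrl 1.

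Gabpb2 was nearly lost from the dKO cells. It fell from 33.5 ± 4.34 CPM in Ctrl to 2.75 ± 0.142 CPM in dKO (SD, n = 2), which is 12.2-fold lower (log2 fold change -3.61, SE 0.26, edgeR adjusted p = 0.00126). Raw Gabpb2 counts were 1244 and 1009 in the Ctrl libraries and 85 and 86 in the dKO libraries. Gabpb1 was at 54.6 ± 3.60 CPM in Ctrl and 80.3 ± 1.25 CPM in dKO, and the difference did not pass (log2 fold change 0.56, SE 0.17, edgeR adjusted p = 0.273). A count over the whole gene cannot separate the long Gabpb1 form named by the genotype from other forms, so it checks nothing about that allele. Gabpa did not pass either (log2 fold change 0.30, SE 0.16, edgeR adjusted p = 0.578). Adjusted over the list of 3 GABP subunits alone, 1 rose (Gabpb1) and 1 fell (Gabpb2). On GRCm38 the genes lie on chromosome 3 from 95181766 to 95217916 (Gabpb2, ENSMUSG00000038766), chromosome 2 from 126627442 to 126676337 (Gabpb1, ENSMUSG00000027361) and chromosome 16 from 84834925 to 84863779 (Gabpa, ENSMUSG00000008976).

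Transcripts of the sex chromosomes separated the groups completely. Xist, the RNA that silences an X chromosome in females, had 6066 and 6430 counts in the Ctrl libraries and 2 and 9 counts in the dKO libraries. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 counts in both Ctrl libraries. Ddx3y reached 251 ± 38.4 CPM in dKO, 2810-fold higher than the floor of 3 counts per library in Ctrl. Against the same floor Eif2s3y was 834-fold higher, Kdm5d 517-fold and Uty 385-fold. These bounds would be lower if each fragment was counted more than 1 time. All 5 passed in edgeR, with adjusted p between 4.34e-05 and 0.000183. The labels give no sex, and every difference between Ctrl and dKO described here lies between libraries that also differ in these markers.

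**Figure D1:**
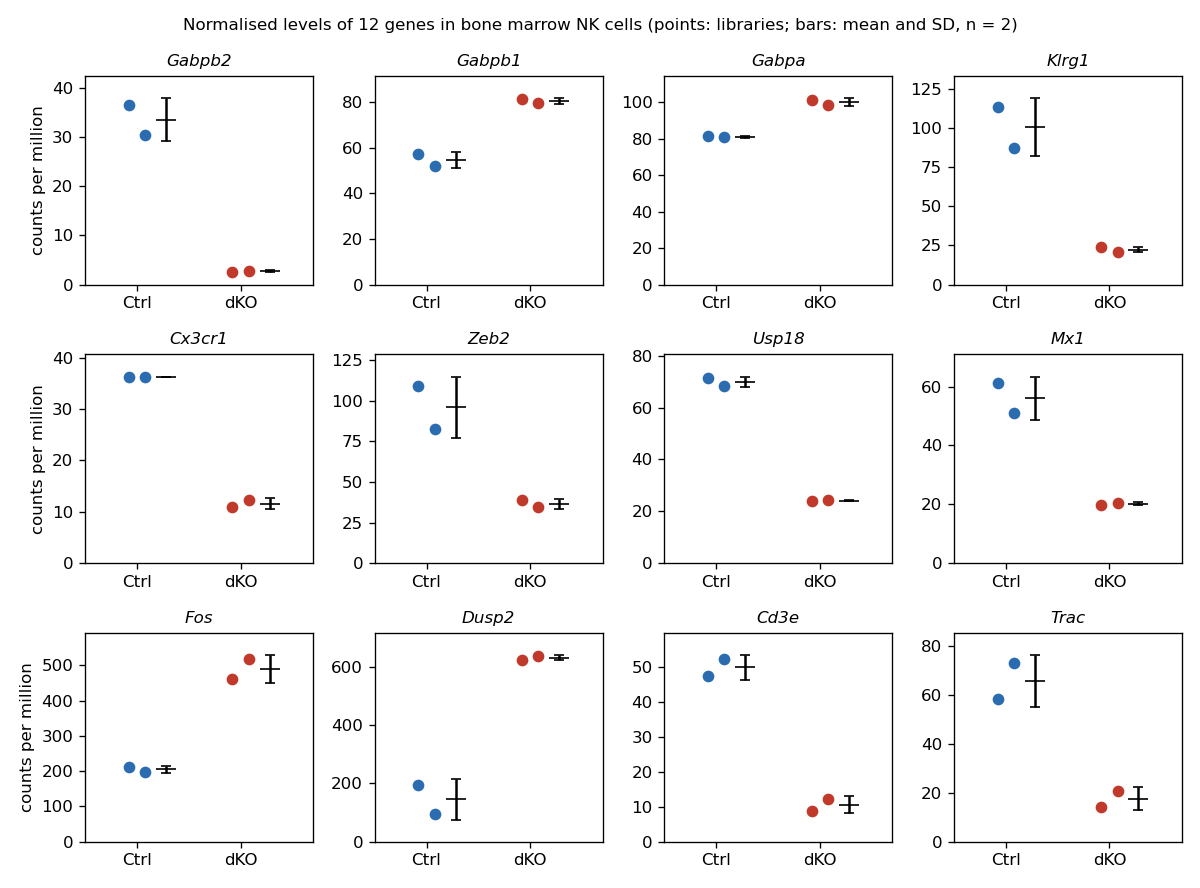
Normalised levels (CPM, axes from 0) of 12 genes in the Ctrl and dKO libraries, with points for libraries and black bars for the mean and SD of 2 libraries. Gabpb2 was at 33.5 in Ctrl and 2.75 in dKO, and the groups did not overlap for any gene drawn.

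In all, 85 of 13904 tested genes changed, 44 higher and 41 lower in dKO (edgeR, adjusted p under 0.05), and 83 of them by at least 2-fold. The unadjusted p was under 0.05 for 1470 genes. Akr1c12, an aldo-keto reductase gene, had the highest fold outside the Y chromosome among the genes that met the naming rule, at 2.87 ± 0.474 CPM in Ctrl and 73.6 ± 12.9 CPM in dKO (log2 fold change 4.68, SE 0.26, adjusted p = 0.000202). Its close relative Akr1c13 rose by 2.24 on the log2 scale (SE 0.19), and reads of these similar copies may not be separable. Hpse, which encodes the enzyme heparanase, rose from 6.60 ± 1.71 to 98.7 ± 7.99 CPM (log2 fold change 3.90, SE 0.25, adjusted p = 0.000502). Cno (3.63, SE 0.32), the ephrin gene Efnb1 (2.98, SE 0.35), Tmem87a (2.28, SE 0.18, and 2.95 with RSEM counts), the phosphatase gene Dusp2 (2.13, SE 0.31) and Acbd6 (2.13, SE 0.26) were the other genes that the rule named as higher. After Xist and Gabpb2, the lower genes were BC094916 (log2 fold change -2.35, SE 0.34), Tyms (-2.35, SE 0.36), the gamma T cell receptor constant region Tcrg-C (-2.31, SE 0.23), the actin regulator gene Cyfip1 (-2.27, SE 0.22), Cd3e (-2.24, SE 0.24), Fubp3 (-2.22, SE 0.27), Klrg1 (-2.16, SE 0.21), Trac (-1.90, SE 0.25), Slfn1 (-1.81, SE 0.24) and the nucleoside transporter gene Slc28a2 (-1.78, SE 0.19). By position, 72 of the changed genes lay on chromosomes 1 to 19 (35 higher, 37 lower), 6 on X and 4 on Y, and 3 had no GRCm38 position. The number of changed genes was 559 without the count filter, 148 with a stricter filter, 398 with DESeq2 and 187 without Ctrl replicate 2.

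Of 20 tested markers of mature NK cells, 4 fell and none rose: Klrg1, an inhibitory receptor of late-stage NK cells, from 100.4 ± 18.4 to 22.4 ± 1.86 CPM (log2 fold change -2.16, SE 0.21, edgeR adjusted p = 0.00560), the chemokine receptor Cx3cr1 (-1.65, SE 0.22, adjusted p = 0.0209), the mast cell protease gene Cma1 (-1.41, SE 0.21, adjusted p = 0.0337) and the transcription factor Zeb2, which drives late NK maturation (-1.39, SE 0.20, adjusted p = 0.0296). In total 11 fell adjusted over the list alone, and 19 of the 20 had a negative log2 fold change with a median of -0.59. As a set the list was lower than other genes (camera adjusted p = 1.57e-09), but did not pass with an estimated correlation (adjusted p = 0.767). Fry, which tests a list against no change rather than against other genes, gave an adjusted p = 0.140. Itgam, the CD11b gene, did not pass (log2 fold change -0.62, SE 0.22, adjusted p = 0.377). Cx3cr1 and Cma1 missed the threshold without dKO replicate 1 (adjusted p = 0.0549 and 0.0677), and Zeb2 missed it without Ctrl replicate 1 or dKO replicate 2 (adjusted p = 0.0582 and 0.0679).

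Markers of immature NK cells gave no call among 19 tested (edgeR), and adjusted over the list alone 3 rose and 1 fell. Ltb (log2 fold change 0.58, SE 0.14, adjusted p = 0.172) and Ctla2a (0.66, SE 0.17, adjusted p = 0.209) had the smallest p, and Cd27 was at 299 ± 12.02 CPM in Ctrl and 390.2 ± 32.8 CPM in dKO (adjusted p = 0.415). The set test of this list gave a camera adjusted p = 0.478. Among 29 NK transcription factors, 3 fell: Ikzf2, which encodes the Ikaros-family factor Helios, from 59.9 ± 8.32 to 18.7 ± 1.99 CPM (log2 fold change -1.68, SE 0.21, edgeR adjusted p = 0.0172), Zeb2, and the interferon regulatory factor Irf8 (-0.98, SE 0.15, adjusted p = 0.0337). Adjusted over the list alone, 1 rose and 3 fell, and the camera adjusted p was 0.287. Irf8 missed the threshold without dKO replicate 1 (adjusted p = 0.0677) or dKO replicate 2 (0.0873), and without dKO replicate 2 only 1 of the factors was called. The lineage factors Tbx21 (log2 fold change -0.29, SE 0.15, adjusted p = 0.559) and Eomes (0.16, SE 0.20, adjusted p = 0.860) did not pass.

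NK receptors and effector genes gave no call at the threshold over all genes (edgeR). Of 28 receptor genes, Klra1 (log2 fold change -0.99, SE 0.22, adjusted p = 0.128) and Slamf7 (-0.74, SE 0.19, adjusted p = 0.201) had the smallest p, adjusted over the list alone 0 passed, and the camera adjusted p was 0.422. Klra1 belongs to a family of similar receptor genes whose reads may not be separable. Ncr1 and Klrb1c, which encode the NK receptors NKp46 and NK1.1, were at 1608 ± 264 and 1763 ± 188 CPM in Ctrl and 1403 ± 15.8 and 1474 ± 50.8 CPM in dKO (adjusted p = 0.756 and 0.627). Of 22 effector genes, 18 had a negative log2 fold change, and adjusted over the list alone 1 rose and 4 fell. Gzma was at 1772 ± 428 CPM in Ctrl and 955 ± 189 CPM in dKO (log2 fold change -0.89, SE 0.21, adjusted p = 0.160), the protease gene Ctsc had -0.54 (SE 0.14, adjusted p = 0.209), and the perforin gene Prf1 had -0.51 (SE 0.14, adjusted p = 0.224). Gzmb, the granzyme B gene, did not pass (log2 fold change -0.21, SE 0.17, adjusted p = 0.752). The effector set was lower than other genes at a camera adjusted p = 0.0215, against adjusted p = 0.979 with an estimated correlation, and missed the threshold without Ctrl replicate 1 (0.523) or dKO replicate 1 (0.221).

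Of 20 migration genes, Cx3cr1 fell, and adjusted over the list alone 5 fell. The set gave a camera adjusted p = 0.00685, against adjusted p = 0.767 with an estimated correlation, and 0.0968 without dKO replicate 1. In IL-15 receptor signalling, the pathway that keeps NK cells alive, none of 23 genes was called, adjusted over the list alone 4 rose and 1 fell, and the camera adjusted p was 0.803. Jak3 was at 258 ± 7.21 CPM in Ctrl and 152 ± 7.29 CPM in dKO (log2 fold change -0.77, SE 0.15, edgeR adjusted p = 0.0790), and the kinase gene Pim2 had 0.97 (SE 0.21, adjusted p = 0.122). Il2rb (-0.28, SE 0.16), Bcl2 (0.19, SE 0.21) and Mcl1 (0.06, SE 0.17) did not pass, with adjusted p of 0.627, 0.821 and 0.945. Of 26 apoptosis regulators, the pro-apoptotic gene Bmf fell from 13.6 ± 1.95 to 3.49 ± 0.302 CPM (log2 fold change -1.96, SE 0.31, adjusted p = 0.0386), adjusted over the list alone 2 fell, and the camera adjusted p was 0.465. Bmf was not called without dKO replicate 1 (adjusted p = 0.0768) or dKO replicate 2 (0.123).

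Of 30 tested interferon-stimulated genes, 3 fell (edgeR): Usp18, which restrains interferon signalling, from 69.9 ± 1.99 to 24.1 ± 0.141 CPM (log2 fold change -1.54, SE 0.18, adjusted p = 0.0137), the antiviral gene Mx1 (-1.47, SE 0.20, adjusted p = 0.0235) and Ifit1 (-1.34, SE 0.19, adjusted p = 0.0279). When adjusted over the list alone, 17 fell, and all 30 had a negative log2 fold change with a median of -0.74. The set was lower than other genes (camera adjusted p = 9.99e-15), but did not pass with an estimated correlation (adjusted p = 0.767). Against no change, the fry test gave an adjusted p = 0.140. Mx1 missed the threshold without dKO replicate 1 or 2 (adjusted p = 0.0519 and 0.0512), and Ifit1 without Ctrl replicate 1 (0.0519), dKO replicate 1 (0.0747) or dKO replicate 2 (0.0634). The number of members called was 13 without the count filter, 12 with DESeq2, 6 with a stricter filter and 1 without dKO replicate 1.

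Immediate early genes, which cells switch on within minutes of a stimulus, held 5 genes that rose among 25 tested (edgeR). Fosb rose from 2.11 ± 0.164 to 16.3 ± 2.43 CPM (log2 fold change 2.95, SE 0.32, adjusted p = 0.00790) and Fos from 204 ± 10.2 to 490 ± 39.0 CPM (1.26, SE 0.15, adjusted p = 0.0144). Dusp2 rose from 145 ± 71.1 to 632 ± 8.85 CPM (2.13, SE 0.31, adjusted p = 0.0286), Klf4 by 2.22 on the log2 scale (SE 0.35, adjusted p = 0.0386) and Jun from 179.8 ± 31.03 to 385.6 ± 24.05 CPM (adjusted p = 0.0386). Adjusted over the list alone 5 rose and 1 fell, and 9 of the 25 had a negative log2 fold change. The set gave a camera adjusted p = 0.0215, against adjusted p = 0.767 with an estimated correlation, and missed the threshold without Ctrl replicate 2 (0.172) or dKO replicate 1 (0.221). Dusp2, which lies 0.660 Mb from Gabpb1, had a log2 fold change of 2.74 without Ctrl replicate 1 and 1.698 without Ctrl replicate 2. It missed the threshold without dKO replicate 1 or 2 (adjusted p = 0.116 and 0.107) and Jun without Ctrl replicate 2 or dKO replicate 1 (0.0575 and 0.0633), and called members numbered 2 without dKO replicate 1 and 3 without dKO replicate 2. Klf4, named after its values were seen, was not called without Ctrl replicate 1, dKO replicate 1 or dKO replicate 2, with limma-voom or with the RSEM counts.

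The S-phase and G2/M lists were lower as sets (camera adjusted p = 8.33e-09 and 4.25e-09), and did not pass with an estimated correlation (adjusted p = 0.979 for both). Tyms, the thymidylate synthase gene, fell from 25.1 ± 4.40 to 4.94 ± 2.28 CPM (log2 fold change -2.35, SE 0.36, edgeR adjusted p = 0.0379) and was the only call among 35 S-phase genes, 33 of which had a negative log2 fold change. It missed the threshold without Ctrl replicate 1 (adjusted p = 0.0534) and with the RSEM counts (0.0527). Of the S-phase genes, 1 rose and 11 fell adjusted over the list alone. None of 32 G2/M genes was called, all 32 had a negative log2 fold change with a median of -0.80, and adjusted over the list alone 7 fell. Kif11 (-1.08, SE 0.28, adjusted p = 0.192) and the proliferation marker Mki67 (-0.80, SE 0.21, adjusted p = 0.198) had the smallest p there. Mpo and Elane, markers of precursor cells that divide in the marrow, also had negative log2 fold changes (-1.97 and -1.99, neither past the threshold). The neutrophil list that holds them had a median of -0.07. In Ctrl 1 and Ctrl 2, Mpo was at 348 and 104 CPM and Elane at 106 and 39.4 CPM. Kif11 (124 and 87.1 CPM) and Mki67 (104 and 95.6 CPM) were less uneven. Both cell cycle sets stayed lower without Ctrl replicate 1. Replication-dependent histones had no call among the 26 of 70 listed genes that were tested (camera adjusted p = 0.661). Hist2h2be (-1.31, SE 0.43) and Hist1h1e (1.27, SE 0.44) were weakly expressed, with group means of at most 5.23 CPM.

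**Figure D2:**
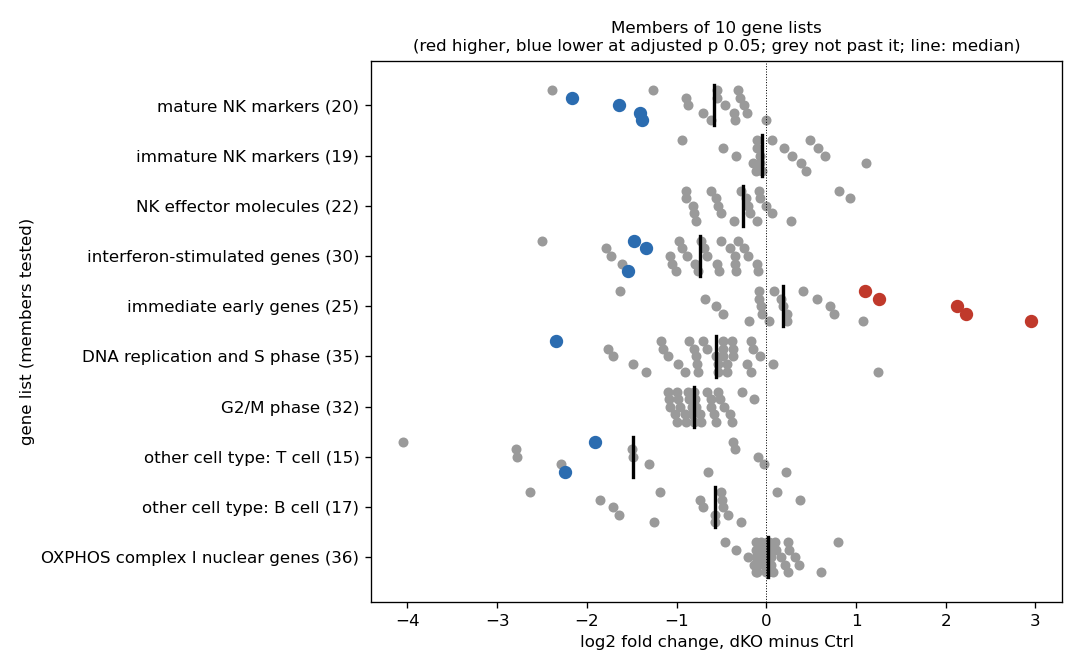
Log2 fold changes (dKO minus Ctrl, horizontal axis) of the tested members of 10 gene lists, with 1 point per gene, colour for genes past an edgeR adjusted p of 0.05 and a black line at the list's median. All 30 interferon-stimulated genes and all 32 G2/M genes lay below 0, while the complex I genes had a median of 0.02.

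Mitochondrial genes, which include known GABP targets, gave no call (edgeR). The largest list, 74 mitochondrial ribosomal proteins, had a median log2 fold change of -0.06 (camera adjusted p = 0.358), with Mrps26 at 0.35 (SE 0.19) and Mrpl19 at -0.37 (SE 0.21). Among 36 complex I genes the median was 0.02 (camera adjusted p = 0.973; Ndufab1 -0.46, SE 0.24; Ndufb8 0.36, SE 0.22). Among 25 genes of complexes II to IV it was 0.07 (camera adjusted p = 0.706; Cox5b 0.82, SE 0.24; Uqcrc1 -0.27, SE 0.15). ATP synthase genes had camera adjusted p = 0.800 (Atp5b -0.30, SE 0.17; Atp5g1 -0.38, SE 0.22), and the 12 tested mitochondrial genome transcripts 0.803 (mt-Cytb -0.45, SE 0.24; mt-Atp8 0.38, SE 0.26). The genome transcripts passed as a set in opposite directions with 1 library left out, higher without dKO replicate 1 (0.0318) and lower without dKO replicate 2 (0.000429). Mitochondrial gene expression and import had camera adjusted p = 0.965 among 33 genes, but passed the fry test for changes in either direction (adjusted p = 0.0157). In that list Lonp1, a mitochondrial protease gene, was at 4.77 ± 0.271 CPM in Ctrl and 11.2 ± 0.397 CPM in dKO (log2 fold change 1.23, SE 0.29, adjusted p = 0.156), and Polg had 0.56 (SE 0.19, adjusted p = 0.320). In these 6 lists, 0 genes passed adjusted over the list alone.

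Cytosolic ribosomal protein genes were higher as a set, with 77 of 83 positive, a median log2 fold change of 0.33 and a camera adjusted p = 0.00620, against adjusted p = 0.979 with an estimated correlation. None passed singly (edgeR; Rps27 1.02, SE 0.32, and Rpl8 1.03, SE 0.33). The direction of this set turned without Ctrl replicate 2 (camera adjusted p = 0.686) and without dKO replicate 2 (0.192), and these genes have many near-identical copies whose reads may not be separable. Glycolysis genes were lower as a set, with 16 of 19 negative (camera adjusted p = 0.0215, against adjusted p = 0.767 with an estimated correlation), and none passed singly. Slc16a1, a lactate transporter gene, had -0.72 (SE 0.21, adjusted p = 0.253) and Pfkp -0.46 (SE 0.14, adjusted p = 0.284). The glycolysis set missed the threshold without Ctrl replicate 1 (0.133) or dKO replicate 1 (0.179).

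The remaining metabolic, translation and stress lists had no changed member and no set call with camera. Their camera adjusted p was 0.388 for aminoacyl-tRNA synthetases (Iars2 0.86, SE 0.23; Aars -0.44, SE 0.14), 0.422 for translation factors (Eif2s3x -0.64, SE 0.22; Eif3j -0.83, SE 0.30, which passed with RSEM counts), 0.287 for the proteasome (Psmb4 0.98, SE 0.29; Psmb2 -0.38, SE 0.18) and 0.439 for the TCA cycle (Idh3a -0.39, SE 0.18; Mdh2 -0.31, SE 0.14). It was 0.439 for fatty acid oxidation (Cpt1a 0.69, SE 0.43; Eci2 0.28, SE 0.20), 0.422 for cholesterol synthesis and 0.800 for antioxidant defence (Gclm 0.96, SE 0.33; Prdx5 0.38, SE 0.15). It was 0.0910 for the integrated stress response (Mthfd2 -1.34, SE 0.30; Ppp1r15a 0.91, SE 0.19), 0.973 for p53 targets (Plk3 1.68, SE 0.40; Pmaip1 -1.40, SE 0.32), 0.358 for heat shock (Hspd1 -0.47, SE 0.20; Hsp90ab1 -0.45, SE 0.21) and 0.287 for ILC1 and ILC2 markers (Ctla2a 0.66, SE 0.17; Cxcr6 -0.97, SE 0.30). Adjusted over the list alone, 1 rose and 1 fell in the integrated stress response and in p53 targets, and 0 passed in the others. Over all 42 lists tested as sets, 11 passed with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.767. For immediate early genes and glycolysis the estimated correlation (-0.0068 and -0.016) was below the preset 0.01. Their unadjusted camera p still rose from 0.0056 to 0.091 and from 0.0054 to 0.094. A higher correlation was not the reason there, and with 4 libraries a miss does not show that a list stayed unchanged. In the other lists that passed, the estimated correlation was above the preset, from 0.0321 for migration to 0.918 for G2/M. It was 0.816 for cytosolic ribosomal proteins, 0.603 for S phase, 0.376 for B cells and 0.254 for T cells. For such lists the preset counts members that move together as nearly independent, which makes the camera p smaller. The median, mean and camera direction of the log2 fold changes differed in sign for immature NK markers, IL-15 signalling, apoptosis regulators, ATP synthase, mitochondrial genome transcripts, mitochondrial gene expression and import, antioxidant defence and stroma or endothelium, none of which passed. The fry test gave 0 lists moving one way (smallest adjusted p = 0.140) and 14 lists with changes in either direction.

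Of 15 tested T cell markers 2 fell in the dKO libraries, although the sort excluded cells with surface CD3e. Cd3e fell from 49.99 ± 3.53 to 10.6 ± 2.37 CPM (log2 fold change -2.24, SE 0.24, edgeR adjusted p = 0.00790) and the alpha receptor constant region Trac from 65.7 ± 10.6 to 17.5 ± 4.57 CPM (-1.90, SE 0.25, adjusted p = 0.0207). Adjusted over the list alone 8 fell, and the median was -1.49 (camera adjusted p = 2.11e-07, against adjusted p = 0.767 with an estimated correlation and 0.185 with fry). Cd247 was at 225 ± 8.83 CPM in Ctrl and 177 ± 7.62 CPM in dKO (adjusted p = 0.462) and Trbc2 at 357 ± 36.6 and 276 ± 51.3 CPM (adjusted p = 0.538), and these members, picked after their values were seen, did not pass. Without dKO replicate 2, 7 markers were called lower. The 2 dKO libraries in which Cd3e, Trac, Klrg1, Usp18 and Tyms were lower were also those with Y-linked transcripts and with a higher share of reads outside annotated genes (23.8% and 24.3%, against 18.1% and 21.5% in Ctrl).

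B cell markers were lower as a set (camera adjusted p = 0.00170, against adjusted p = 0.979 with an estimated correlation), with 15 of 17 negative, none called singly and 1 lower adjusted over the list alone. Igll1 was at 3.98 ± 2.09 CPM in Ctrl and 0.637 ± 0.199 CPM in dKO (adjusted p = 0.145), and Pax5 at 2.02 ± 1.07 and 0.615 ± 0.254 CPM. The B cell set missed the threshold without Ctrl replicate 2 (0.637). The neutrophil precursor genes Mpo and Elane were uneven within Ctrl, at 226 ± 173 and 72.5 ± 46.7 CPM, and at 57.6 ± 2.98 and 18.3 ± 3.69 CPM in dKO, with neither past the threshold (adjusted p = 0.155 and 0.112). Adjusted over the list alone, 2 neutrophil genes fell, and the camera adjusted p was 0.175. Among plasma cell markers Irf4 had -1.99 (SE 0.35, adjusted p = 0.0564) and Sdc1 -2.12 (SE 0.50, adjusted p = 0.151), with 1 higher and 3 lower adjusted over the list alone and a camera adjusted p = 0.212. Dendritic cell markers held 1 call, Irf8, which is also in the list of NK transcription factors (camera adjusted p = 0.287; 1 lower adjusted over the list alone). No call was made in the lists for monocytes or macrophages (C1qc 1.38, SE 0.34, and Mrc1 -0.45, SE 0.22; camera adjusted p = 0.752), erythroid cells (Car2 -0.38, SE 0.15, and Hba-a2 -0.40, SE 0.31; 0.287), basophils or mast cells (Hdc -0.67, SE 0.27, and Prss34 0.61, SE 0.50; 0.800), progenitors (Angpt1 0.90, SE 0.26, and Ly6a -2.02, SE 0.64; 0.440) and stroma or endothelium (Pecam1 -0.69, SE 0.23, and Sparc -1.67, SE 0.92; 0.657), or adjusted over each of those lists alone.

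Changed genes gathered around Gabpb1 on chromosome 2. Within 10 Mb on either side, 10 of 199 tested genes changed (5.03%), 4 higher and 6 lower, against 62 of 12736 (0.487%) on the rest of chromosomes 1 to 19 (Fisher's exact test, two-sided p = 1.39e-07, odds ratio 10.8). The 10 genes were Bmf, 5430417L22Rik, 1700020I14Rik, Tmem87a, Ttbk2, Mfap1b, Slc28a2, Gm14085, Dusp2 and Acoxl, of which the 6 others than Bmf, Tmem87a, Slc28a2 and Dusp2 were chosen after their values were seen. On GRCm38 they reached from 118528757 (start of Bmf) to 128123873 (end of Acoxl). The acyl-CoA oxidase-like gene Acoxl, 1.16 Mb from Gabpb1, fell from 6.90 ± 2.04 to 0.438 ± 0.223 CPM (log2 fold change -3.97, SE 0.54, edgeR adjusted p = 0.0231). Gm14085 lies near Slc28a2 and had 1 and 4 counts in Ctrl and 251 and 221 counts in dKO, while Slc28a2 was at 181 ± 32.3 CPM in Ctrl and 52.8 ± 2.999 CPM in dKO. Mfap1b has a close relative nearby and was not called with the RSEM counts (adjusted p = 0.578). Within 10 Mb of Gabpb2, 1 of 233 tested genes changed, Gabpb2 itself. Without genes on X and Y, 75 genes changed. Without those within 10 Mb of Gabpb1 or Gabpb2, 74 changed. Without both groups, 64 changed, 33 higher and 31 lower.

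**Figure D3:**
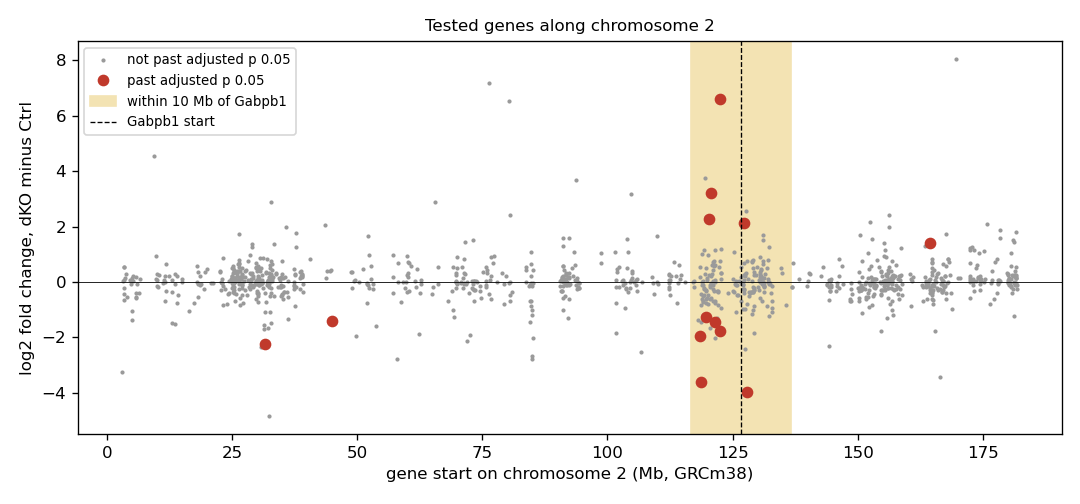
Log2 fold change (dKO minus Ctrl, vertical axis) of each tested gene against its start on chromosome 2 (horizontal axis, Mb, GRCm38), with genes past an edgeR adjusted p of 0.05 in red and the region within 10 Mb of Gabpb1 shaded. The shaded region holds 10 changed genes and the rest of the chromosome 3.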

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

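All tests in this part were chosen after the results they bear on had been seen. The share of counted reads outside any annotated gene was higher in the dKO libraries, at 23.8% in dKO 1 and 24.3% in dKO 2, than in the Ctrl libraries, at 18.1% and 21.5%. These reads lie outside the gene counts, and the share also differed between the 2 Ctrl libraries. With 2 libraries against 2, groups separate by chance in 33.3% of cases, so a difference between groups is not shown.

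Sex-linked transcripts followed genotype, with Xist in both Ctrl libraries and Y-linked genes in both dKO libraries. Wrong genotype labels are argued against by Gabpb2, whose lowest Ctrl level was 10.7 times its highest dKO level. A candidate explanation is that the Ctrl animals were female and the dKO animals male: Ctrl had 0 Y-linked counts, and the highest Xist level of a dKO library was 0.160% of the Ctrl mean. For the 61 changed genes on chromosomes 1 to 19 other than Gabpb2 and those within 10 Mb of Gabpb1, sex and genotype cannot be told apart, because no library of either group matches the sex markers of the other. Genotype stays open as well.

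Changed genes gathered around Gabpb1. Chance placement is argued against by the excess inside the region (Fisher's exact p = 1.39e-07) and by windows around other autosomal genes. Of 12681 such windows, 0 held as many calls and the highest held 5. Genes near enough to Gabpb1 on chromosome 2 for the windows to overlap were left out. Reads shared between gene copies are argued against as the main cause, since 9 of the 10 genes kept direction and call with RSEM counts, all but Mfap1b. Those counts come from the same reads, so they cannot show whether reads that were not aligned play a part. A chromosome segment that travelled with the modified Gabpb1 allele may account for the cluster, and so may local action of the changed allele on its neighbours. The low share of calls on the rest of chromosome 2 (0.326% of its genes) cannot tell these apart. Both would leave it low, and that share restates the gathering itself. Dusp2 and Acoxl lay 0.660 and 1.16 Mb from Gabpb1. The other called genes lay 4.10 (Gm14085) to 8.08 Mb (Bmf) away, all at lower coordinates, with no call between Gm14085 and Dusp2. This spacing argues against action on near neighbours alone, but does not exclude action over a longer distance.

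Of 15 T cell markers 2 fell in dKO, and the set call was lost at adjusted p = 0.767 with an estimated correlation. Less RNA from all other cell types alike is argued against by the 104 markers of the other cell types listed, whose median log2 fold change was -0.25 (median absolute deviation 0.529) against -1.49 for the T cell list. The B cell markers had a median of -0.57. Fewer T cells in the dKO sorts may account for the pattern, which would lower Cd3e, Cd3d, Cd3g, Trac, Cd5 and Cd6 by a common factor if the NK cells held none of these RNAs. The 6 folds differed in a chi-square test of heterogeneity over the edgeR SEs at p = 0.0446, a value that ran from 0.0230 to 0.114 with any 1 gene left out, and that condition was added after the first p was seen. Neither a change within NK cells nor fewer T cells is thereby excluded, and sex and genotype stay open.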

How the results depend on the processing

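Of the alternatives below, the removal of genes on X and Y or near Gabpb1 and Gabpb2 was chosen after seeing the data. All 36 named genes past the threshold kept their direction in every alternative fit run for them. With the threshold kept at an adjusted p of 0.05, 484 of 504 values lay on the same side of it, 20 were past it no longer and 26 genes were called in all of these fits. In every changed gene both dKO libraries lay on the same side of both Ctrl libraries, so leaving out 1 library could hardly turn a sign. The 85 changed genes kept their sign wherever tested. Of these, 73 remained called with limma-voom, 80 with RSEM counts, 85 with DESeq2, and 67, 77, 58 and 58 without Ctrl 1, Ctrl 2, dKO 1 and dKO 2. Where a group was left with 1 library, it was assumed to vary like the other group. Of 78 named genes not past the threshold, 74 kept their sign everywhere, and some passed the threshold in an alternative fit. Scaling by library size only gave 103 changed genes, of which 56.3% were higher. Camera does not use DESeq2, limma-voom or the robust setting, so these gave no set tests. The self-test found 54.3% of planted 2-fold changes, all placed in the better expressed genes. Depth and 2 libraries per group therefore leave many changes of that size uncalled, and weakly expressed genes were not covered.

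Changed genes numbered 85 (44 higher, 41 lower). They were 559 (256 and 303) without the filter, where 23322 genes were tested, 148 (73 and 75) with a stricter filter, 398 (183 and 215) with DESeq2 and 24 at an adjusted p of 0.01. Leaving out 1 library gave 73 to 187 (31 to 94 higher, 32 to 93 lower), with 187 without Ctrl replicate 2. Lists with a changed member were 9, but 27 without the filter, 23 with DESeq2 and 7 to 19 with 1 library left out. Mature NK markers lower were 4, but 10 and 8 without the filter and with DESeq2, and 2 to 5 with 1 library left out. Interferon-stimulated genes lower were 3, but 13, 12 and 6 without the filter, with DESeq2 and with the stricter filter, and 1 to 3 with 1 library left out. T cell markers lower were 2, but 8, 7 and 4 in the same order, 4 with limma-voom, 4 with RSEM counts and 2 to 7 with 1 library left out. Immediate early genes higher were 5 (2 to 4 with 1 library left out) and NK transcription factors lower 3 (1 to 3). Set calls were lost for ribosomal proteins and immediate early genes without the filter (0.0898 for both), for glycolysis (0.0893) and B cells (0.233) with the stricter filter and for effectors with RSEM counts (0.0603). Set tests past the threshold were 11, but 0 with an estimated correlation and 0 with fry. Apart from the fewer libraries or the other gene numbers, the cause was not tested.

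Reversed values were the log2 fold changes of mt-Atp8 with RSEM counts (-0.0236), of Bcl2 without Ctrl replicate 1 (-0.0498; range over the left-out libraries up to 0.48), and of Prss34 (-0.43, up to 1.21) and Eomes (-0.0239, up to 0.31) without dKO replicate 2. The ribosomal protein set reversed without Ctrl replicate 2 (camera adjusted p = 0.686) and dKO replicate 2 (0.192), over a range from 1.69e-12. The mitochondrial genome set reversed without dKO replicate 1 (0.0318), over a range from 0.000429 to 0.903. The cause was not tested.

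The replicate number as a block gave 100 changed genes (48 higher, 52 lower), 5 interferon-stimulated genes and 5 T cell markers lower. With the block 80 of the 85 genes remained called, and Irf8 (adjusted p = 0.0786), Ripk3, Cdk16, Nfkbiz and Phf20l1 were not. The labels do not say that equal numbers share a litter or day, and deviations of same-numbered samples correlated at -0.0544 across genes, so the samples were not treated as pairs.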

Other observations

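The tests and genes in this part were chosen after the values were seen. Among the changed genes outside the fixed lists, the guanylate-binding protein genes Gbp6 (log2 fold change -1.47, SE 0.17, edgeR adjusted p = 0.0111) and Gbp10 (-1.68, SE 0.24, adjusted p = 0.0287) and the GTPase gene Iigp1 (-1.70, SE 0.28, adjusted p = 0.0465) were lower in dKO. Gbp10 was not called without dKO replicate 1, and Iigp1 was not called with limma-voom or without Ctrl replicate 1, dKO replicate 1 or dKO replicate 2. The Gbp genes are similar copies, so their values are uncertain. Ripk3, a kinase gene of necroptosis, fell from 141 ± 17.3 to 65.7 ± 0.795 CPM (log2 fold change -1.11, SE 0.17, adjusted p = 0.0357), and was not called without Ctrl replicate 1, dKO replicate 1 or dKO replicate 2.

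The RSEM gene length of Gabpb1, a mean over its transcripts weighted by their estimated shares, was 1407 and 1707 bases in the Ctrl libraries and 1202 and 994 bases in the dKO libraries (log2 ratio -0.50). Among 5507 genes with a mean of at least 500 expected counts, 0.0545% had a lower log2 ratio. The length of Gabpb2 moved the other way, from 4936 and 4717 bases in Ctrl to 5835 and 7274 bases in dKO (log2 ratio 0.44). Of the same genes 99.9% had a lower ratio, but Gabpb2 had only 41.2 and 36.2 expected counts in dKO. The length of Gabpa was 3351 and 3457 bases in Ctrl and 3259 and 3082 bases in dKO.

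X-linked genes known to be expressed from both X chromosomes in females did not pass (edgeR): Kdm6a had a log2 fold change of -0.73 (SE 0.17, adjusted p = 0.151), Eif2s3x -0.64 (SE 0.22, adjusted p = 0.332), Kdm5c -0.47 (SE 0.25, adjusted p = 0.578), 2610029G23Rik -0.27 (SE 0.22, adjusted p = 0.754) and Ddx3x 0.16 (SE 0.25, adjusted p = 0.896). The unadjusted edgeR p was 0.00272 for Kdm6a and 0.0183 for Eif2s3x, and above 0.05 for the other genes of this group. The 438 tested X genes had a median of -0.05, and the autosomal genes 0.01.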
